A study of Mus musculus with 23 samples.

How the data were processed

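Liver DNA methylation was measured by reduced representation bisulfite sequencing (RRBS), in which genomic DNA is cut with MspI at CCGG sites, size-selected, treated with bisulfite so that unmethylated cytosines read as thymine, and sequenced. The 23 libraries each came from the liver of an individual mouse, per the labels. They fall into 4 groups: 6 control males and 5 control females with a floxed Stat5a-Stat5b locus, and 6 males and 6 females in which an albumin promoter-driven Cre had removed STAT5a and STAT5b from hepatocytes (STAT5ab-KO, written KO from here on). Per the labels' protocols the floxed line was of mixed C57BL/6 and 129J background and the Cre transgenic line was FVB/N. The animals were young adults. The sample titles carry 5 different codes whose meaning is not given in the sources used here, and the comparisons could not be adjusted for them, since the table has no per-animal values. A single code was carried by both control males and control females, and another by both KO males and KO females, while KO and control libraries of the same sex shared none.

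The authors deposited a single table of 3885 regions of 100 bp, each with 4 columns of differences in percent methylation. Per the file legend, a region was listed where the absolute difference between the groups exceeded 15 percentage points at a q-value under 0.05, and a positive value marks higher methylation in the first-named group of control males against control females, KO males against KO females, KO males against control males, or KO females against control females. The table writes the non-knockout groups as WT, and these were taken to be the floxed controls, which are the only non-knockout mice in the labels. A value of 0 in a column marks a region that was not listed for that comparison. It does not separate a region with a small difference from a region that was not covered or did not pass the q-value. In the values themselves no nonzero difference was smaller in size than 15.01 points, no region appeared more than once, and all regions lay on the 19 autosomes. Per the submitters' processing notes the build was mm9, and Trim Galore 0.4.3, Bismark and methylKit were used. The coverage minimum, the way replicates entered the test and the role of each tool are not given in the sources used here. A region's difference and its call therefore rest on the authors' own model, with n of 5 or 6 animals per group. The table used here gives no methylation level, coverage, q-value or per-animal value, so the depth behind a difference is unknown and no standard deviation between animals can be attached to it.

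Coordinates are printed as the table gives them, in mm9. A genome or annotation of that build was not used here, and the gene table at hand is of another assembly (GRCm38.p6). Regions are therefore identified by position only. The gene lists fixed beforehand could not be applied, and neither could classes of gene position or chromatin.

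The following were computed from the deposited differences. The split of higher and lower regions in each comparison was tested against equal numbers with a two-sided exact binomial test, with exact Clopper-Pearson 95% intervals and Benjamini-Hochberg adjustment over the 4 comparisons. The splits of males and females were compared with Fisher's exact test (two-sided). For each of the 6 pairs of comparisons, the regions listed in both were counted, the association of directions was tested with Fisher's exact test, and Pearson's r and Spearman's rho were computed across regions with 100000 permutations, each adjusted over the 6 pairs. Regions are not independent replicates. These p-values and intervals describe the regions of the table and not the spread between animals. For each pair, the share of same directions that arises with no effect was simulated from normally distributed group values of equal spread, scaled so that the median size beyond 15 points matched the table. The number of regions tested by the authors is not in the table, so no expected number of shared regions was computed. A region was said to have a group apart where that group differed in the same direction from both groups it was compared with and the other 2 comparisons were not listed. The share expected from the overall splits of a pair of lists multiplies the odds of the needed direction in each list, as if the directions were independent.

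The rule set before the data were examined named the 10 largest higher and the 10 largest lower differences of each comparison by gene. As no gene is assigned, the same 10 were taken by position. Giving the first 3 in full and the rest as a range was decided after the data were seen, as was the ranking, by the smaller of both differences, of regions listed in a pair of comparisons and of regions with a group apart. The alternatives set before the data were examined and run here were a stricter absolute difference of at least 25 points and the merging of neighbours within 10 kb that share a direction. The simulated values, the comparison of gain and loss at sex-differing regions, the regions with a group apart, tests of single chromosomes, tests of blocks along chromosomes, tests with chromosomes as units, and the removal of regions within 5 Mb of a region with opposite KO changes in the sexes were added after the data were seen. The block tests compared sets of regions with 10000 random draws of the same size. The scripts were tested on simulated data. The direction test on 2153 regions made 6 false calls in 100 tables with no effect. Where an effect was simulated, it was found in 100 of 100 tables. The block test on 385 regions made 2 false calls and found 100 of 100. Its planted regions were picked for lying within 5 Mb of chosen ones, the distance the test counts, so detection was close to fixed. That check also used unmerged regions and fewer draws than the block tests reported here. Simulated directions were drawn independently for each region, whereas neighbouring regions here mostly share a direction. The false-call rate of the direction test may therefore not hold for these data. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.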

Results

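STAT5a and STAT5b are the transcription factors that carry the growth hormone signal to liver genes, and the plasma pattern of growth hormone differs between male and female mice. DNA methylation was compared in liver of control mice and of mice lacking both factors in hepatocytes, in males and females, so that sex differences and the effect of STAT5 loss could each be measured in the other's presence and absence. The libraries came from 6 control males, 5 control females, 6 KO males and 6 KO females. The authors' deposited table held 3885 regions of 100 bp with a called difference in at least 1 of 4 comparisons, and 5437 called differences in all. Most regions (2629) were listed in a single comparison, 1031 in 2, 154 in 3 and 71 in all 4. Differences are in percentage points of methylation, positions are in mm9, and the read depth behind each difference is unknown.

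The comparison of KO males with control males gave the longest list. Methylation was higher in KO males than in control males at 1467 regions and lower at 686, so that 68.1% of the 2153 listed regions gained methylation (95% exact interval 66.1 to 70.1). The median gain was 20.5 points (interquartile range 17.4 to 25.5) and the median of the losses was -19.5 points. In the authors' deposited table, the 3 largest gains were at chromosome 3, 119802001 to 119802101 (58.8 points), chromosome 4, 140775701 to 140775801 (55.2 points), and chromosome 2, 172805601 to 172805701 (54.9 points), and the other 7 of the 10 largest reached down to 46.1 points. The 3 largest losses in the authors' deposited table were at chromosome 11, 88289701 to 88289801 (-58.9 points), chromosome 5, 76133701 to 76133801 (-51.2 points), and chromosome 11, 84777601 to 84777701 (-50.2 points), with the tenth at -42.8 points. The longest runs of neighbouring regions were 5 regions with a mean gain of 25.1 points on chromosome 16, 24391901 to 24395101, and 5 regions with a mean of -18.2 points on chromosome 5, 111848201 to 111849501. The excess of gains over losses was larger than an equal split would give (exact binomial test, adjusted p = 3.14e-64), and gains outnumbered losses on all 19 chromosomes. On chromosome 2, 145 of 171 regions gained methylation (84.8%), a higher share than on the other chromosomes (Fisher's exact test on merged neighbours, adjusted p = 0.000133 over 76 tests).

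In female liver the list was shorter and the excess of gains smaller. KO females were higher than control females at 665 regions and lower at 427, a share of 60.9% gains among 1092 regions (57.9 to 63.8; exact binomial test, adjusted p = 1.2e-12). The median gain was 20.9 points and the median of the losses -21.5 points. The largest gains in the authors' deposited table were at chromosome 11, 41553601 to 41553701 (55.3 points), chromosome 1, 154460401 to 154460501 (54.4 points), and chromosome 11, 62520801 to 62520901 (53.1 points), and the tenth was 43.3 points. The largest losses that the authors' deposited table gives for females were at chromosome 11, 115664901 to 115665001 (-73.3 points), chromosome 6, 121969701 to 121969801 (-68.9 points), and chromosome 1, 167789201 to 167789301 (-67.2 points), with the tenth at -51.3 points. On chromosome 14, 44 of 69 regions were lower in KO females, a larger share than on the other chromosomes (Fisher's exact test on merged neighbours, adjusted p = 0.00767 over 76 tests). Gains outnumbered losses on 16 of 19 chromosomes. Among differences of at least 25 points, the share of gains in females was 55.7% and did not pass the test against an equal split (exact binomial test, adjusted p = 0.0578).

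The balance of gains and losses differed between the sexes. Gains made up 68.1% of the male list and 60.9% of the female list, an odds ratio of 1.37 (95% interval 1.18 to 1.60; Fisher's exact test, p = 4.66e-05). With regions listed in both sexes left out, the shares were 67.1% and 55.4% and the odds ratio was 1.64. With chromosomes as units the male share was higher on 13 of 19 chromosomes, by 7.07 points on average (exact sign-flip test, p = 0.0151). The male list was 1.97 times as long as the female list. A difference in list length was not tested, since the control female group had 5 animals against 6 in the others and the coverage of each group is unknown.

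**Figure D1:**
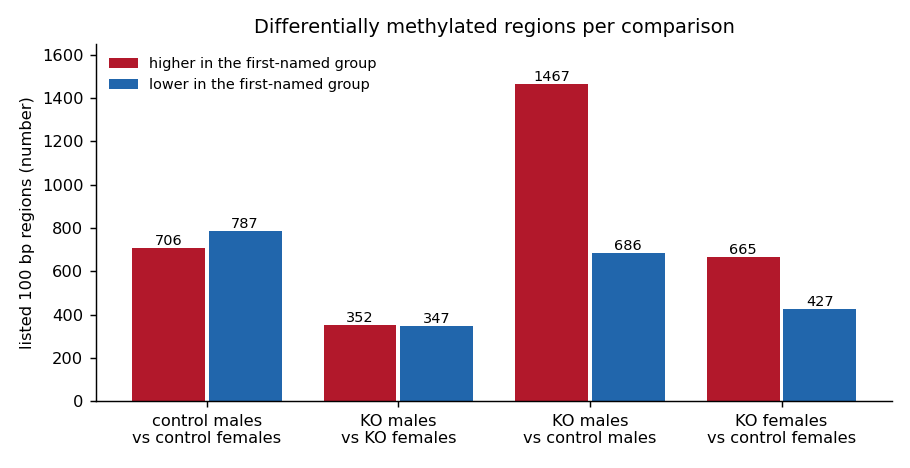
Number of listed 100 bp regions (vertical axis) with higher (red) and lower (blue) methylation in the first-named group of each of the 4 comparisons. Gains outnumber losses in KO males (1467 against 686) and KO females (665 against 427), while the 2 comparisons between the sexes lie closer to an equal split (706 against 787 in controls and 352 against 347 in KO mice).

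Regions called in both sexes mostly changed the same way. Of 385 regions listed in both KO comparisons, 238 gained methylation in both sexes and 69 lost it in both, so that 79.7% moved in the same direction (75.4 to 83.6; Fisher's exact test, adjusted p = 2.87e-21). These comparisons have no library in common, and independent directions with the same shares of gains in each sex would give 59.6% (simulated unchanged groups with equal gains and losses, 50.1%). By the authors' deposited table, the regions with the largest gains in both were at chromosome 11, 107126701 to 107126801 (52.4 points in males and 40.0 in females), chromosome 5, 123220901 to 123221001 (38.03 and 39.57 points), and chromosome 3, 18146401 to 18146501 (49.4 and 37.2 points). The largest losses in both, again from the authors' deposited table, were at chromosome 1, 174464001 to 174464101 (-41.0 points in males and -46.4 in females), chromosome 1, 167789201 to 167789301 (-33.3 and -67.2 points), and chromosome 3, 39720801 to 39720901 (-45.6 and -32.8 points). Across the 385 regions the male and female differences were correlated (Pearson's r = 0.44, Spearman's rho = 0.38, permutation p = 1e-05 for each, the smallest the permutations can give, and 1.2e-05 adjusted over 6 pairs), with a covariance of 250.4 squared points against 1.22 in the simulation. Within the regions that gained in both sexes rho was 0.35, and within those that lost in both it was 0.08. The listing threshold of 15 points leaves a gap around 0 in these values. The simulated groups were drawn independently, so the simulated share and covariance were fixed by that choice. A title code was carried by both control sexes and another by both KO sexes, and strain background may differ between KO and control mice. A library or background effect that goes with genotype could also give shared directions, which was not tested.

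At the other 78 regions the change had opposite signs in the sexes. KO males gained and KO females lost methylation at 43 of them, and the reverse held at 35. At chromosome 18, 77252701 to 77252801, the authors' deposited table gives 40.7 points for KO males and -37.1 points for KO females. At chromosome 8, 130443001 to 130443101, the changes in the authors' deposited table were -38.7 points in males and 32.3 points in females, and at chromosome 6, 129885001 to 129885101, they were 37.3 and -33.7 points. Most of these regions (72) were also listed between control males and control females, and 54 had listed sex differences of opposite sign in controls and in KO mice. Opposite KO changes beyond the listing threshold put the control and KO sex differences far apart by arithmetic. The selection of these regions therefore favours both counts, which are not separate findings. The 78 regions were unevenly placed: 13 lay on chromosome 11, 13 on chromosome 18, 11 on chromosome 4 and 11 on chromosome 6. On chromosome 18, between 70680401 and 84332501, 8 of 9 units (neighbours within 10 kb merged) were higher in KO males and lower in KO females, and no region listed there had the same change in both sexes. Whether the sexes differed at a given region was not tested, because the table holds no per-animal values.

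**Figure D2:**
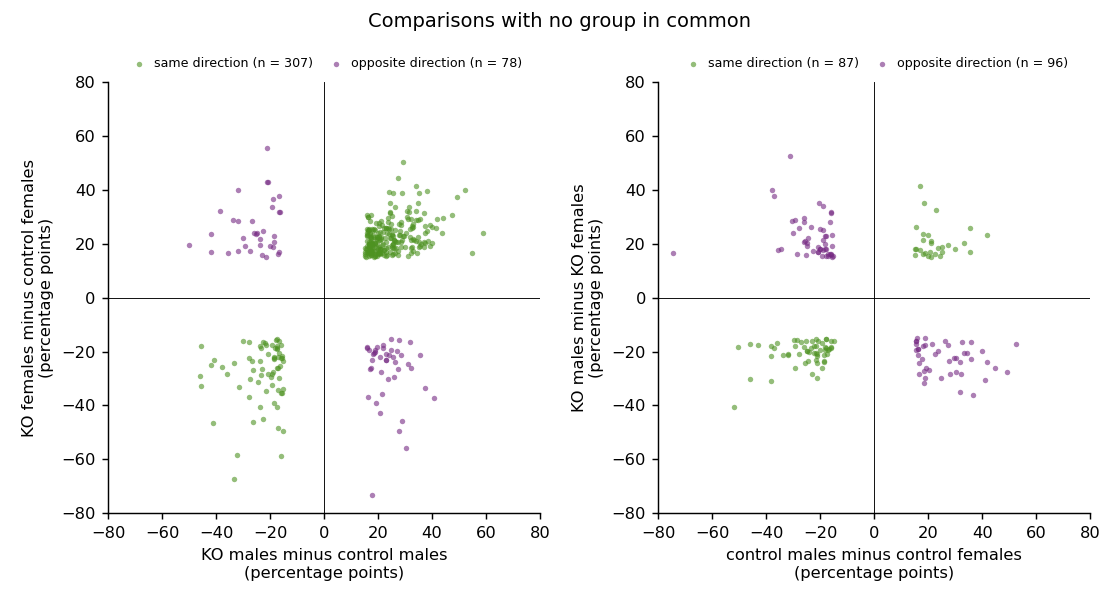
Differences in percentage points at regions listed in both comparisons, for KO males minus control males against KO females minus control females (left, 385 regions) and for control males minus control females against KO males minus KO females (right, 183 regions). Each point is a region, green where the signs are the same and purple where they are opposite: the left panel has 307 green and 78 purple points, the right panel 87 and 96.

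**Figure D3:**
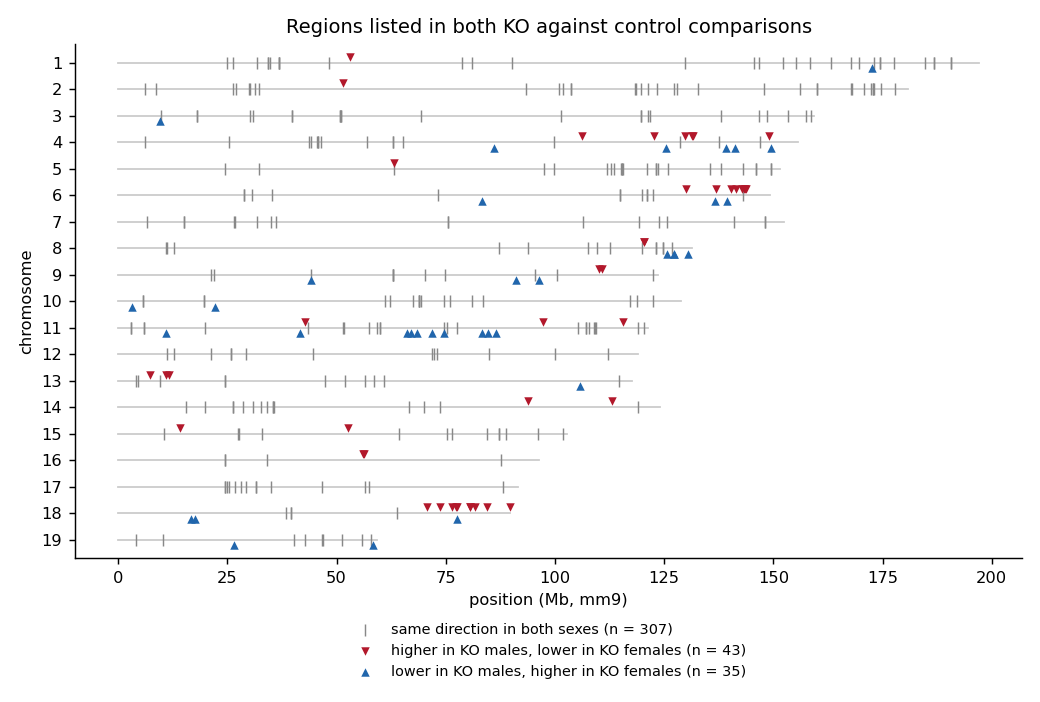
Position in Mb (mm9) along the 19 autosomes of regions listed in both KO against control comparisons: grey ticks changed in the same direction in both sexes (307), red triangles were higher in KO males and lower in KO females (43), blue triangles the reverse (35). Red triangles gather on distal chromosomes 6 and 18 and blue triangles on chromosome 11, where 13 of the 78 lie.

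More regions were listed between the sexes in control liver than in KO liver. This difference in list length was not tested, since the control female group had 5 animals against 6 in the others and coverage is unknown. Control males and females differed at 1493 regions, with higher methylation in males at 706 and in females at 787. The share higher in males was 47.3% (44.7 to 49.9), which did not pass the test against an equal split after adjustment (exact binomial test, adjusted p = 0.0512). Among differences of at least 25 points the share was 43.1% and passed (exact binomial test, adjusted p = 0.0194). The largest male-higher differences in the authors' deposited table were at chromosome 11, 62520801 to 62520901 (65.7 points), chromosome 11, 71858601 to 71858701 (63.4 points), and chromosome 14, 72926401 to 72926501 (60.04 points). The largest female-higher differences in the authors' deposited table were at chromosome 11, 115664901 to 115665001 (-74.5 points), chromosome 14, 121299001 to 121299101 (-69.9 points), and chromosome 6, 121969701 to 121969801 (-67.9 points). The tenth largest of each direction were 49.2 and -52.1 points.

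KO males and KO females differed at 699 regions, 0.47 times the number in controls, with 352 higher and 347 lower in males (50.4%, 46.6 to 54.1; exact binomial test, adjusted p = 0.88). In the authors' deposited table the largest of these were at chromosome 18, 84332401 to 84332501 (60.7 points), chromosome 6, 141549001 to 141549101 (52.6 points), and chromosome 14, 35507201 to 35507301 (41.3 points), and, lower in males, at chromosome 4, 148490601 to 148490701 (-42.3 points), 140100301 to 140100401 (-41.9 points) and 139197101 to 139197201 (-41.0 points). The tenth largest were 35.2 and -35.7 points.

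Most of the sex-differing regions of controls, 1310 of 1493 (87.7%), were not listed between KO males and KO females, and 516 of the 699 KO sex differences (73.8%) were not listed in controls. Of the 183 regions listed in both, 87 kept the direction of the sex difference and 96 had the opposite one (47.5% the same, 40.1 to 55.0; Fisher's exact test, adjusted p = 0.363), and the correlation of the sizes did not pass its test (Pearson's r = -0.11, permutation p = 0.125; Spearman's rho = -0.12, permutation p = 0.108, both also after adjustment). With regions within 5 Mb of the 78 opposite-sign regions left out, 69 of the remaining 94 (73.4%) kept their direction. That removal takes out 54 regions with opposite KO changes, all of which had opposite sex differences, an outcome that opposite changes of over 15 points each favour by arithmetic. At a minimum of 25 points in both comparisons the result went the other way, with 23.8% of 21 regions keeping their direction (Fisher's exact test, adjusted p = 0.0244). Opposite sex differences of that size favour opposite KO changes by the same arithmetic, so this set overlaps the 78 regions. An example is chromosome 18, 77252701 to 77252801 (-37.8 points in controls and 40.0 in KO mice). The overlap was not counted. Being unlisted is not a measured loss of the sex difference, since the table gives no value there.

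Some regions with a sex difference in controls were also listed between KO and control mice. A shared control group can by itself favour listing in both, and no expected number was computed. KO males differed from control males at 454 of the 1493 regions, and at 406 of them (89.4%) the change was toward the female level: 282 female-higher regions gained methylation and 124 male-higher regions lost it. KO females differed from control females at 419, and at 389 of them (92.8%) the change was toward the male level: 195 male-higher regions gained methylation and 194 female-higher regions lost it. In the 282 regions the median sex difference was -22.3 points and the median gain in KO males was 23.0 points. In the 195 regions the median sex difference was 21.8 points and the median gain in KO females 23.8 points. Each of these pairs of comparisons uses the same control libraries, and simulated unchanged groups that share a control group gave 96.4% and 95.9%, so that the shares of 89.4% and 92.8% do not exceed what a shared group gives alone. Pearson's r was -0.73 for males and 0.85 for females against simulated values of -0.89 and 0.89, and the covariances were -428.3 and 622.5 squared points against simulated values of -501.2 and 515.6. For the KO sex difference, 249 of 277 regions also listed in KO males had the same direction in both (89.9%, simulated 96.4%), and 172 of 201 regions also listed in KO females had opposite directions (85.6%, simulated 95.7%).

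Among the sex-differing regions that moved toward the other sex, gains made up 69.5% in KO males and 50.1% in KO females, an odds ratio of 2.26 (1.69 to 3.02; Fisher's exact test, p = 3.34e-08). Independent directions with the overall splits of the lists would give 70.4% in males and 58.3% in females. The female share was lower than that value (exact binomial test, adjusted p = 0.00356) and the male share did not differ from it at the threshold (adjusted p = 0.664). The lists compared within each sex share a control group, so their directions were not independent. That value is therefore not what unchanged groups would give, and these p-values decide no explanation.

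**Figure D4:**
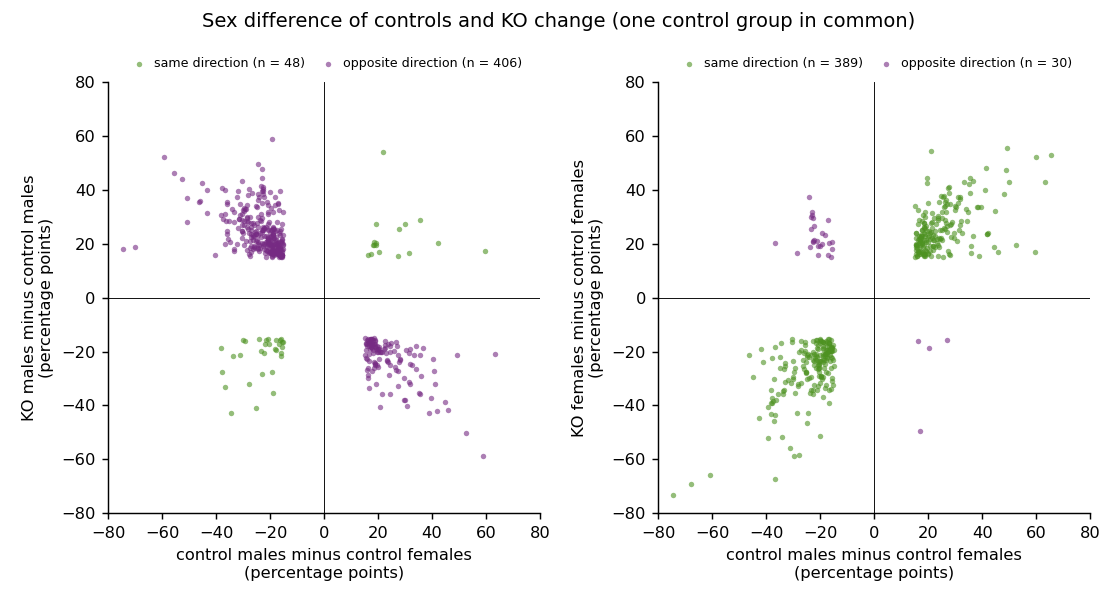
Differences in percentage points between control males and control females (horizontal axes) against the change in KO males (left vertical axis, 454 regions) and in KO females (right vertical axis, 419 regions). Points are regions, purple for opposite and green for same signs; the left panel shares the control males and the right panel the control females between its axes, which alone gives 96.4% and 95.9% in the predominant quadrants.

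A single group stood apart from both groups it was compared with at 748 regions, a control group at 524 and a KO group at 224. Control males stood apart at 275 regions and were the lower group at 199 of them (72.4%, 66.7 to 77.6; exact binomial test, adjusted p = 2.87e-13). At chromosome 6, 149138201 to 149138301, the authors' deposited table gives -59.2 points for control males against control females and 52.3 points for KO males against control males. At chromosome 3, 108632501 to 108632601, the values in the authors' deposited table were -55.7 and 46.1 points, and at chromosome 18, 70525201 to 70525301, they were -52.6 and 43.8 points. Control females stood apart at 249 regions and were lower at 140 (56.2%; exact binomial test, adjusted p = 0.114), KO males at 149 and were lower at 83 (55.7%; adjusted p = 0.253), and KO females at 75 and were lower at 39 (52%; adjusted p = 0.818). The excess of lower regions was larger for control males than for control females (odds ratio 2.04, 1.42 to 2.93; Fisher's exact test, p = 0.000121). With independent directions, the overall splits of both lists involved would put control males lower at 70.4% of such regions and control females at 58.3%. For KO males that value would be 31.6% and for KO females 39.4%. The observed share was above that value for KO males (55.7%; exact binomial test, adjusted p = 8.96e-09) and did not differ from it at the threshold for control males (adjusted p = 0.625), control females (adjusted p = 0.625) and KO females (adjusted p = 0.0656).

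**Figure D5:**
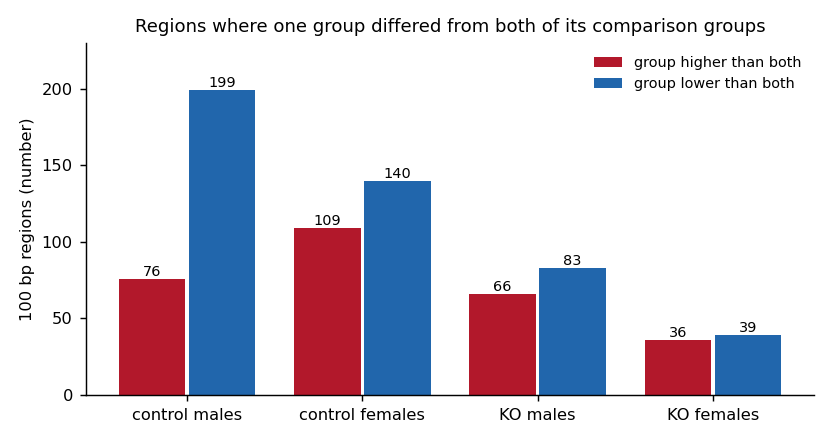
Number of 100 bp regions (vertical axis) at which one group was higher (red) or lower (blue) than both groups it was compared with, the other 2 comparisons being unlisted. Control males were lower at 199 regions and higher at 76, and KO females were split nearly evenly, 39 against 36.

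The 71 regions listed in all 4 comparisons gave a measure of how well the columns fit each other, since the KO sex difference must equal the control sex difference plus the male KO change minus the female KO change if each group has a single level. At 44 of the 71 the values closed within 0.05 points. At 18 they were off by over 5 points, and by 33.0 points at most. In the authors' deposited table, chromosome 1, 163254901 to 163255001, had 59.62 points between control sexes and KO changes of 17.3 (males) and 16.86 (females). A single level per group would make its unlisted KO sex difference large. At chromosome 1, 127782801 to 127782901, only the control sex difference was listed (-59.39 points). By the same rule, the unlisted ones could not all be under the listing threshold. Unlisted values, also at regions with a group apart, can thus be large.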

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

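The comparison of directions between the sexes and the count of same and opposite changes were set before the data were examined. The comparison of gains with losses at sex-differing regions and all tests of explanations in this part were chosen only after the results were seen.

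The share of regions with higher methylation after STAT5ab loss differed between the sexes, with an odds ratio of 1.37 for males against females. Gains were more frequent relative to losses in males than in females at control sex-differing regions that moved toward the other sex. The odds ratio was 2.26 (1.69 to 3.02). Independent directions with the overall splits of the lists would give 1.71. The lists share control groups and were not independent, so 1.71 is not a no-effect value. At 78 regions the change with STAT5ab loss had opposite signs in the sexes, and the difference between the sexes was not tested region by region.

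The opposite changes were gathered along chromosomes. Of their 76 units, 65.8% had another within 5 Mb, against a mean of 38.3% in random draws from regions listed in both KO comparisons (p = 0.0001, the smallest the draws can give), and 75.7% of neighbouring units had the same orientation against 49.7% with orientations shuffled (permutation p = 0.0015), which argues against library differences that act regardless of position. A candidate explanation that gives this clustering is strain haplotypes: the mice were of mixed background, and long segments from different strains could have fallen unequally into the 4 small groups. No genotype was analysed here, so a sex-dependent effect of STAT5 on chromosomal domains stays open, and it was not tested.

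Control males were the lower group at 72.4% of the regions where they stood apart. The excess of gains in the KO male list alone gives 68.1%, from which the control-male share did not differ at the threshold (exact binomial test, p = 0.137). The low control-male values may be that excess seen again. All regions where control males stood apart are part of that list, however, and rest on the same control libraries. The test therefore cannot tell whether that excess gives the low control-male values or the reverse. The same excess would put KO males lower at 31.9% of the regions where they stood apart, against 55.7% observed (exact binomial test, p = 2.93e-09). Those regions also had to be listed between the KO sexes, a comparison with the same KO male libraries, so 31.9% is not a no-effect value. The excess as an explanation therefore stays open. Noise skewed downward in all groups also stays open, since it would raise the share lower, as seen in KO males. Control females were lower at 56.2% against 58.3% expected from the list splits. That expected value takes directions as independent in lists that share libraries, so it cannot decide this. A code in the titles was carried by 4 of the 6 control males and by no other group. Another was carried by 5 of the 6 KO females alone, and these were lower at 52% of the regions where they stood apart. A library effect and a lower level particular to control male liver stay open, and neither was tested.

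More regions gained than lost methylation in KO liver of both sexes. Higher readings in the KO male libraries alone or lower readings in the control male libraries alone would leave KO females balanced against control females, where 60.9% were gains, though at 25 points or more the share was 55.7% and did not pass its test (exact binomial test, adjusted p = 0.0578). They would also tilt the sex comparisons, and regions higher in males were 50.4% between KO sexes and 47.3% between control sexes, though the control value fell to 43.1% at 25 points or more, so a part from the control males in the male list stays open. The meaning of the codes in the titles is not stated: 0 codes were shared by KO and control libraries of the same sex and 1 was carried by both genotypes, in control females and KO males, groups that the table does not compare, so if the codes mark batches, batch and genotype cannot be told apart without per-animal values. The floxed and Cre lines were also of different strain backgrounds, so background may differ between KO and control mice, which was not tested. An effect of STAT5 loss on methylation stays open beside these.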

How the results depend on the processing

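Removal of regions within 5 Mb of an opposite-sign region, tests with chromosomes as units and removal of regions listed in both sexes were chosen only after the results were seen, while the 25-point minimum and the merging of neighbours within 10 kb were set before, though not for the results on a group standing apart and on gain against loss, which were themselves added later. Of 72 alternative values with a test, 64 kept their direction and their side of the threshold, including all 22 with neighbours merged. Of 12 counts of listed regions, 7 stayed within 1.5 times the count reported, including all 4 with neighbours merged. Part of this tally could hardly come out otherwise. Pairs of comparisons that share a group keep their direction mostly through that group. With the 5 Mb neighbourhoods left out, 100% of 268 regions in both KO comparisons had the same direction, because the opposite-sign regions had been removed. With a minimum of 25 points the lists held 360 (control sexes), 130 (KO sexes), 556 (KO males) and 336 (KO females) regions, by construction. The share higher in control males became 43.1% and passed the test, the share of gains in KO females became 55.7% and no longer passed, 23.8% of 21 regions kept the direction of the sex difference between controls and KO mice and this passed, and KO males standing apart were lower at 42.9% of 21 regions, a reversal that did not pass. For the 23.8%, opposite sex differences of that size favour opposite KO changes by arithmetic, so that set overlaps the opposite-sign regions. The cause of the other shifts was not tested. With the 5 Mb neighbourhoods left out, KO sexes differed at 455 regions, 73.4% of 94 regions kept the direction of the sex difference (rho 0.53), a reversal that follows in part from removing 54 regions whose opposite KO changes favour opposite sex differences by arithmetic, control females standing apart were lower at 60.1%, now past the test, and KO females standing apart were lower at 48.2%, a reversal that did not pass. The cause of the last 2 was not tested. Not run for want of the needed values were a q-value of at most 0.001, coverage of at least 20, at least 3 CpGs, distance to a transcription start site, gene lists, gene position, leaving out replicates, and other splits of the samples. Leaving out sex chromosomes and requiring 50% reciprocal overlap change nothing, since all regions are autosomal and lie on the same 100 bp grid. No paired analysis was possible because the table holds no per-animal values. Depth is unknown, so its limits on the calls cannot be given.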

Other observations

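All tests in this part were chosen only after the results were seen.

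Among the 10 largest differences of each comparison and direction, the number on any single chromosome was compared with 10 regions drawn at random from the same list, in 8 lists, with adjustment over them. Of the 10 largest that were lower in KO males than in KO females, 7 were on chromosome 4 between 134976801 and 148490701, a chromosome that held 16.1% of all regions lower in KO males (adjusted permutation p = 0.00096). Of the 10 largest higher in KO males than in KO females, 5 were on chromosome 18 between 70680401 and 84332501, and of the 10 largest higher in control males than in control females, 5 were on chromosome 11 between 41553601 and 88289801 (adjusted permutation p = 0.0145 for each). The other 5 lists did not pass the test, with 2 to 4 of 10 on a single chromosome. On chromosomes 4, 11 and 18, some of the ranked regions had opposite KO changes in the sexes, which favour large sex differences by arithmetic. The chromosome 18 span is also that of the opposite-sign regions described above. These counts are therefore in part the same regions seen again.

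Of the units with opposite KO changes, 38 fell in 7 blocks of at least 3 units. Besides chromosome 18, the blocks were on chromosome 4 from 122603101 to 131669701, on chromosome 6 from 136647801 to 143781801, on chromosome 8 from 125672201 to 130443101, on chromosome 11 from 66208101 to 74681201 and from 83266001 to 86511701, and on chromosome 13 from 7227401 to 11600701. Within 5 Mb of opposite-sign regions, those regions themselves left out, 18 of 35 regions (51.4%) had the same direction of sex difference in controls and KO mice, and farther away 69 of 94 (73.4%) did (odds ratio 0.384, Fisher's exact test, p = 0.0215). Neighbours were not merged here, and that p-value takes them as independent although adjoining regions mostly share a direction. It therefore decides no effect of the neighbourhood.

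Regions next to each other mostly had the same direction: 110 of 112 adjoining pairs between control sexes, 31 of 31 between KO sexes, 253 of 254 in KO males and 76 of 81 in KO females. Farther apart, the share of pairs with the same direction was compared with shuffled directions in 6 distance bands of each of the 4 comparisons, with adjustment over all of them, where 0.004 comes from the smallest p the shuffles can give. At 0.1 to 1 Mb it was above the shuffled mean in all 4. It was 56.3% against 50.1% between control sexes and 60.9% against 49.9% between KO sexes (adjusted permutation p = 0.004 for each). In KO males it was 59.1% against 55.2% (adjusted permutation p = 0.004). In KO females it was 57.7% against 51.8% (adjusted permutation p = 0.00899). At 0.01 to 0.1 Mb it passed between control sexes (62.6% against 50.2%, adjusted permutation p = 0.0107) and in KO males (63.0% against 55.3%, adjusted p = 0.00685). It did not pass between KO sexes (60.6% against 50.1%, on 66 pairs) or in KO females (59.6% against 51.7%, on 94 pairs). At 1 to 5 Mb it passed between KO sexes (60.2% against 50.0% shuffled, adjusted permutation p = 0.004) and in KO females (54.2% against 51.7%, adjusted p = 0.0432). It did not pass between control sexes (49.7% against 50.0%) or in KO males (55.6% against 55.2%). At 5 to 10 Mb none of the 4 passed, at 10 to 20 Mb the control sexes (52.2% against 50.1%) and KO females (54.3% against 51.7%) did (adjusted permutation p = 0.004 for each), and at 20 to 50 Mb none did.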
